A study of Mus musculus with 6 samples.

How the data were processed

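The series measured, by chromatin immunoprecipitation followed by sequencing (ChIP-seq), where the corepressor KAP1 (encoded by Trim28) binds and where histone H3 carries trimethylation of lysine 9 (H3K9me3) in thymocytes of wild-type mice and of mice that lack KAP1 in T cells. Of the 6 samples, 2 are H3K9me3 immunoprecipitations, 1 per genotype, and these have the region lists used here. The 2 KAP1 immunoprecipitations and the 2 input libraries were not analysed here.

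Per the labels' protocols, freshly isolated thymocytes were cleared of red cells and dead cells and crosslinked with formaldehyde. Chromatin was sonicated, H3K9me3 was precipitated with a polyclonal Diagenode antibody, and libraries were made from size-selected fragments and amplified by PCR. Per the submitters' processing notes, reads were aligned with Bowtie to the mm9 build of the mouse genome; the Bowtie version, its treatment of reads that fit several places, the region caller, its settings and its use of input are not given in the sources used here. The deposited files hold, per region, only its position: a chromosome, a start and an end in base pairs, and a constant strand sign. They give no read count, fold, p-value or score per region, so the sequencing depth and the strength of each region are unknown. Each list belongs to a single library, which does not show how the regions were called. Starts were read as counted from 0, as is usual for this format, and are printed counted from 1.

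The coordinates were checked against a table of GRCm38 gene positions. On 8 chromosomes regions lie past the last gene of that table, so its positions were not used, and no mm9 gene annotation or genome sequence was used here. The planned counts over gene lists (zinc-finger, olfactory, vomeronasal, protocadherin, antigen receptor, imprinted, T cell, KAP1 pathway and other cell type genes) and the planned GC and repeat content of regions were therefore not run, and regions are named by position.

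A wild-type region was counted as shared when at least 1 base of it lay in a knockout region, its partner. Shares of regions are given with Wilson 95% intervals and the ratio of region numbers with an exact binomial interval; these cover counting error only, and treat regions as independent, which clustered regions are not. With 1 library per genotype there is no spread between replicates, so no p-value here tests the genotypes: each describes the lists of these libraries. The overlap was compared with 10000 random placements of the knockout regions, each kept on its chromosome with its width, between the first and last region of either list (one-sided). Mean log2 widths of wild-type regions with and without a partner were compared by a 2-sided permutation test with 100000 resamples and, added later, with 1000 random placements of the knockout regions. Region numbers per chromosome were compared between the lists by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 22 chromosomes. These tests also treat regions as independent. Wild-type regions at most 100 kb apart were joined into neighbourhoods, those with 3 or more regions were called clusters, and their number was compared with 10000 random placements of the wild-type regions. Random placement ignores assembly gaps and unmappable sequence.

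Regions named in the text were fixed by rule before the data were examined, as were most tests and most alternatives: the 8 widest wild-type regions with a partner, the 8 widest without one, the 8 widest knockout regions without a wild-type partner, and the 3 neighbourhoods with most wild-type regions. Other regions named are said to have been chosen later. Alternatives were other overlap rules, wider regions only, autosomes only, joining of neighbours up to 10 kb apart, a wild-type list cut to the length of the knockout list, and other cluster settings; alternatives on a score could not be run, since there is none.

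The procedures were tested on simulated data made from the real lists. Of 100 randomly placed lists, 5 were called as overlapping at a threshold of 0.05, and all 100 lists of 300 planted wild-type regions were called with every region found. The planted regions were exact wild-type regions, so finding them all was fixed in advance and does not show sensitivity to partial overlap. With no change between lists, 1 of 100 simulated lists had a chromosome called; with the share of chromosome X doubled, 94 of 100 had X called. For widths, 5 of 100 random splits and 100 of 100 splits with 0.5 added on the log2 scale were called. The randomly placed lists, chromosome draws and width splits treated regions as independent, unlike the clustered regions of the real lists. Their rates of false calls therefore need not hold for the real lists. The search for recurring arrangements described in the closing section found 0 regions in 1 simulated list with shuffled widths and every region of 100 of 100 copied blocks. The copied blocks were exact copies, so this does not show how well inexact copies are found. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.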

Results

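H3K9me3, a histone mark of heterochromatin, was mapped in thymocytes, the T cell progenitors of the thymus, from wild-type mice and from mice with a T cell-specific knockout of KAP1. KAP1 is a scaffold that KRAB zinc finger proteins bring to DNA and that recruits SETDB1, a methyltransferase of this mark. The series examined which H3K9me3-enriched regions were present with and without KAP1. Each genotype had 1 H3K9me3 library, described by 1 list of enriched regions on the mm9 genome. The lists carry no read counts, so the depth of both libraries is unknown and no value below has a replicate error.

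The wild-type library had many more H3K9me3 regions than the knockout library. The wild-type list held 3748 regions and the knockout list 605, a ratio of 6.20 (95% interval 5.68 to 6.76, counting error only). Wild-type regions covered 11.2 Mb and knockout regions 4.68 Mb, a ratio of 2.39. The median width of the knockout regions was 3232 bp (quartiles 1297 and 8194 bp), against 1292.5 bp (quartiles 591 and 2971 bp) in wild type. Regions of at least 10 kb made up 21.0% of the knockout list (127 regions) and 5.74% of the wild-type list (215 regions). The smallest gap between successive regions was 860 bp in the wild-type and 2054 bp in the knockout list. With neighbours up to 2054 bp apart joined in both lists, a setting added after the data were seen, the median widths were 1317 bp in wild type and 3227.5 bp in the knockout. Regions of at least 10 kb held 70.3% of the bases covered in the knockout and 40.4% of those covered in wild type. With 1 library per genotype, the difference in number could not be tested against variation between animals, and it also depends on the depth and enrichment of each library.

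In the full lists, most H3K9me3 regions of the knockout overlapped one of the wild type, while most wild-type regions had no counterpart in the knockout. Of the 605 knockout regions, 553 overlapped a wild-type region, or 91.4% (Wilson 95% interval 88.9 to 93.4%). Of the 3748 wild-type regions, 656 overlapped a knockout region, or 17.5% (16.3 to 18.8%), and 3092 did not. This share depends on the setting: it was 52.6% among the widest wild-type regions, as many as there are knockout regions, and 9.95% when the overlap had to be 50% of both regions. By length, 4.28 Mb lay in both lists, which was 38.4% of the wild-type and 91.6% of the knockout bases. Random placement of the knockout regions on their chromosomes touched 20.2 wild-type regions on average (95% of draws between 11 and 32), so the observed number was 32.5 times that mean (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). When knockout regions were moved only within 500 kb of their own place, a setting added after the data were seen, 180 wild-type regions were touched on average, and the observed number was 3.63 times that (p = 0.0001, permutation).

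Shared stretches were narrower in the knockout in most cases, though some of the widest wild-type regions overlapped a wider knockout region. Among 444 regions that paired 1 to 1, the knockout region was narrower in 340 and wider in 103. The median knockout width was 0.893 times the wild-type width (log2 ratio -0.16, 95% bootstrap interval -0.24 to -0.10 over pairs; lower quartile -0.70). Starts differed by a median of 255 bp and ends by 215.5 bp, and in 204 pairs (45.9%) both edges lay within 500 bp. These pairs leave out 92 knockout regions that each spanned 2 or more wild-type regions and 9 wild-type regions that held 2 or more knockout regions. Over all 543 shared stretches, formed by linking regions of both lists that overlap (a setting added after the data were seen), the knockout covered fewer bases in 380 and more in 162, with a median log2 ratio of -0.12 (95% bootstrap interval -0.18 to -0.08).

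The 8 widest shared wild-type regions measured 59.3 to 89.0 kb and lay on chromosomes 1, 4, 5, 8 and 11. The widest, on chromosome 8 from 19949064 to 20038028, was 89.0 kb long and overlapped a 120 kb knockout region from 19917276 to 20037740. On chromosome 4, the 76.3 kb region from 146500426 to 146576744 overlapped an 80.5 kb knockout region. That knockout region also spanned the wild-type region from 146496278 to 146498724, so these widths do not compare like stretches. The 73.5 kb region from 145695533 to 145769051 overlapped a knockout region of 72.0 kb. On chromosome 5, a region from 14899771 to 14964159 was 64.4 kb wide in both lists. The region on chromosome 11 from 3025378 to 3100057, 74.7 kb wide, lay over a knockout region of 81.1 kb.

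Wild-type regions without a knockout partner were narrower than those with one. Wild-type regions with a partner had a median width of 4161 bp and those without one 1084 bp. Mean log2 width was 11.92 ± 1.90 (SD, 656 regions) with a partner and 10.12 ± 1.45 (SD, 3092 regions) without, a 3.48-fold difference (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; regions are not replicates). A wide region is touched more readily by any overlapping list, and this test does not allow for that. Placed at random within 500 kb of their own place, in a comparison added after the data were seen, the knockout regions gave a difference in mean log2 width of 1.80 on average (95% of 1000 placements between 1.53 and 2.08), against 1.80 observed (one-sided permutation p = 0.5). Placed anywhere on their chromosome, they gave 0.87 on average (95% of placements between 0.00 and 1.73; one-sided permutation p = 0.02). The width difference thus exceeded placement along whole chromosomes but not local placement, which keeps knockout regions near the wide wild-type regions they overlap. In the narrowest quartile (57 to 591 bp), 6.50% of the wild-type regions had a partner (Wilson 5.10 to 8.27%), against 0.346% under random placement and 1.31% when knockout regions moved within 500 kb. In the widest quartile (2974 to 88965 bp), 42.7% had a partner (39.6 to 45.9%), against 0.927% and 12.0%. Of the 215 wild-type regions of at least 10 kb, 158 had a partner, or 73.5% (67.2 to 78.9%).

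**Figure D1:**
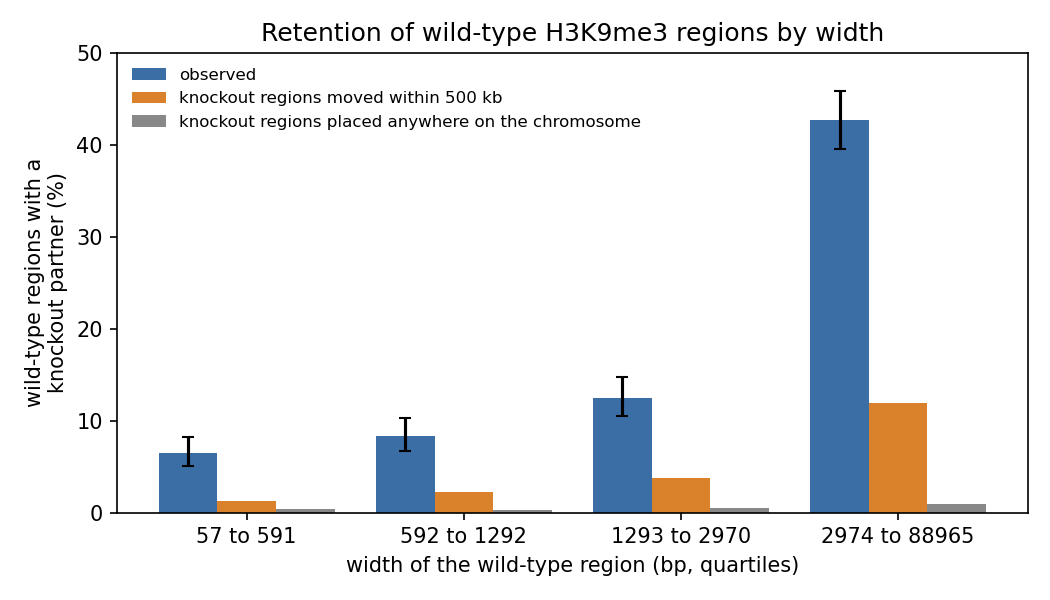
Percentage of wild-type H3K9me3 regions that overlap a knockout region, by quartile of wild-type width in bp. Blue bars are observed shares with Wilson 95% intervals, orange and grey bars are means over random placements of the knockout regions; the observed share goes from 6.50% in the narrowest to 42.7% in the widest quartile.

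Some wide wild-type regions had no knockout counterpart. The 8 widest of these measured 19.1 to 31.8 kb and lay on chromosomes 1, 5, 7 and 17. The widest were a 31.8 kb region on chromosome 5 from 146317909 to 146349747 and a 24.8 kb region on chromosome 17 from 13511953 to 13536751. Within the group of 8, 4 regions of 19.1 to 19.4 kb lay within 1 stretch of chromosome 7, from 33430234 to 33762401. The 52 knockout regions without a wild-type partner were narrow, with a median of 667 bp, and lay a median of 376626 bp from the nearest wild-type region; 15 of them were within 100 kb of one. The widest were a 6.22 kb region on chromosome 8 from 107391355 to 107397574, a 4.55 kb region on chromosome 1 from 103000321 to 103004873 and a 4.32 kb region on chromosome 6 from 124829973 to 124834289.

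By number of regions, a larger share of the wild-type regions had a knockout partner on the sex chromosomes than on the autosomes. On chromosome X, 108 of 245 wild-type regions had a partner, or 44.1% (Wilson 38.0 to 50.3%), and on chromosome Y 47 of 77, or 61.0% (49.9 to 71.2%). On the autosomes together, 500 of 3423 had one, or 14.6% (13.5 to 15.8%), from 1.39% on chromosome 15 to 26.1% on chromosome 4. On chromosome 4, 77 of the 91 regions with a partner lay in its densest neighbourhood, and elsewhere on that chromosome 14 of 192 had one, or 7.29% (Wilson 4.39 to 11.9%). Outside the densest neighbourhood of chromosome X the share was 36.3% (53 of 146). Chromosome X held 6.54% of the wild-type and 12.9% of the knockout regions (Fisher's exact test, adjusted p = 2.8e-06), and chromosome Y held 2.05% and 6.45% (Fisher's exact test, adjusted p = 1.3e-06). By covered length chromosome X did not stand apart from every autosome. Wild-type regions covered 742 kb and knockout regions 571 kb on X, a ratio of 1.30, against 735 kb and 598 kb on chromosome 1, a ratio of 1.23, and 827 kb and 552 kb on chromosome 8. Chromosome 1 held 6.59% of the wild-type and 12.8% of the knockout bases, and X held 6.65% and 12.2%. On chromosome Y the ratio was 1.13. By number of regions, chromosome 5 also had a larger share of the knockout list, 10.7% against 6.96% (Fisher's exact test, adjusted p = 0.011). Chromosomes 12, 13, 14 and 15 had smaller shares of the knockout list (adjusted p = 0.025, 0.047, 0.038 and 0.011, Fisher's exact test); chromosome 15 had 72 wild-type regions and 2 knockout regions. Chromosome 7 had the most wild-type regions of any chromosome, 552, and 70 knockout regions, a share that did not pass the test (14.7% and 11.6% of the lists, Fisher's exact test, adjusted p = 0.095). Fisher's exact test counts clustered regions as independent, so these p-values can be too small: the 77 wild-type regions on Y formed 6 neighbourhoods. The 7 chromosomes called compare the 2 lists, not the genotypes, and 4 of them were called after neighbours up to 10 kb apart were joined (14, 15, X and Y). Without the 3 neighbourhoods that held most wild-type regions, a setting added after the data were seen, 4 were called (5, 15, X and Y).

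**Figure D2:**
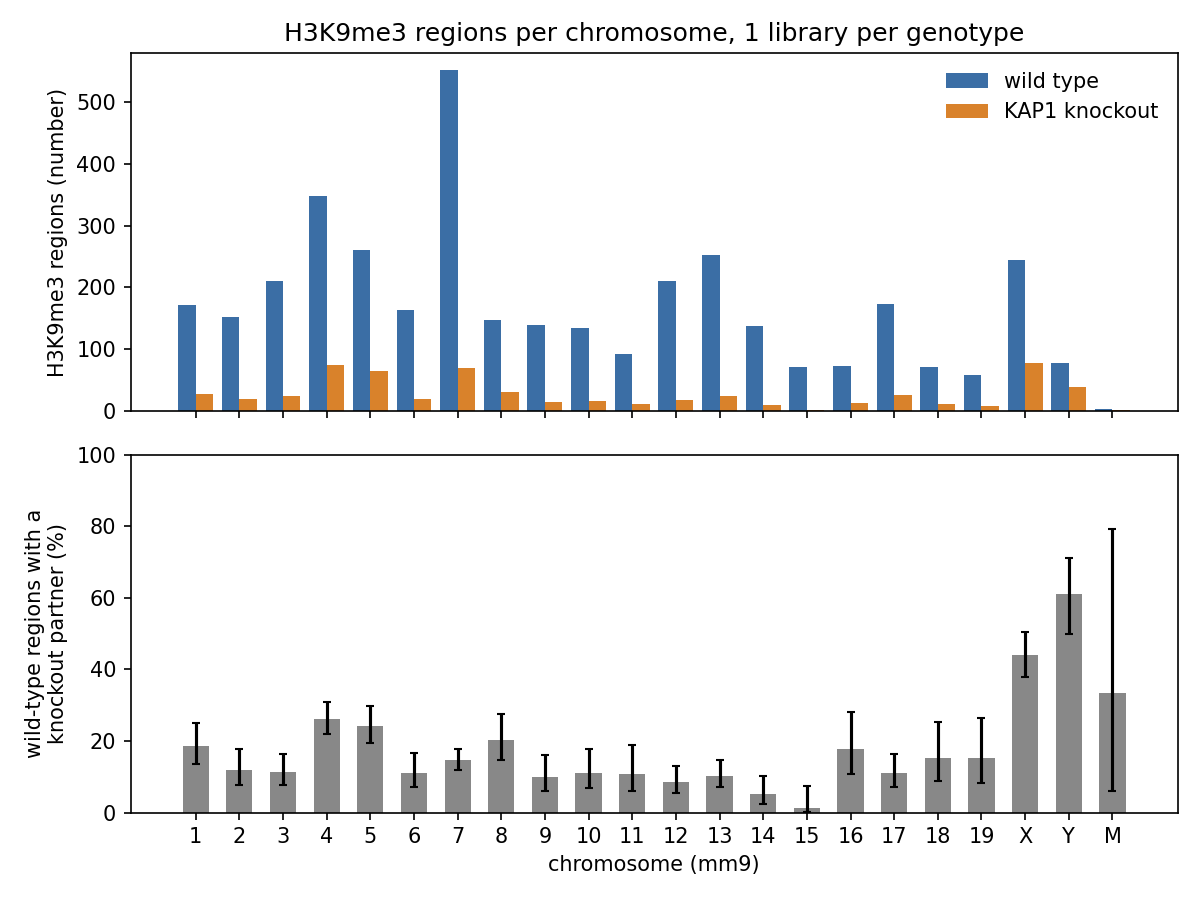
Upper panel, number of H3K9me3 regions per chromosome in the wild-type (blue) and KAP1 knockout (orange) list; lower panel, percentage of wild-type regions that overlap a knockout region, with Wilson 95% intervals for counting error. Chromosome 7 has the most wild-type regions (552), and chromosomes X (44.1%) and Y (61.0%) have higher shares with a partner than any autosome.

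H3K9me3 regions lay in dense groups in both genotypes. The median gap between successive wild-type regions was 31.2 kb, against 402 kb on average under random placement (lowest of 1000 placements 382 kb), and that between knockout regions was 72.9 kb against 2065 kb (lowest 1709 kb). Wild-type regions at most 100 kb apart formed 215 clusters of 3 or more, which held 2311 regions, or 61.7% of the list; random placement gave 98.8 such clusters on average (one-sided permutation p = 1e-04, the smallest that 10000 placements can give). With a limit of 500 kb the comparison turned around: 229 clusters were found, against 433 under random placement. Each called region was placed separately, so a stretch called in several pieces would add to an excess of clusters. Joining neighbours up to 10 kb apart left 2429 of 3748 wild-type regions. The number of clusters was not compared after such joining or with recurring arrangements counted once. Of the 215 clusters, 109 held a region with a knockout partner, or 50.7% (Wilson 44.1 to 57.3%), and 106 held none. Within clusters, 23.5% of wild-type regions had a partner (542 of 2311), against 7.93% outside them (114 of 1437).

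The 3 neighbourhoods with most wild-type regions differed in how much of them the knockout list held. The largest lay on distal chromosome 4 from 144955729 to 147183298, a part of the chromosome known for a large cluster of KRAB zinc finger genes; which regions fall on these genes was not analysed here. It held 156 wild-type regions over 1269 kb of covered sequence, 77 of them with a partner (49.4%), and knockout regions covered 818 kb. On chromosome X, from 120274276 to 121325985, 55 of 99 wild-type regions had a partner (55.6%), and covered length was 243 kb in wild type and 220 kb in the knockout. On chromosome 7, from 32477056 to 34164607, 8 of 73 wild-type regions had a partner (11.0%), and covered length was 265 kb in wild type and 21.3 kb in the knockout. Some wild-type regions in all 3 neighbourhoods recur with the same widths and spacing, a pattern that the closing section describes. On chromosome X, for example, the successive regions starting at 120405915 and 120408571 match those starting at 120856678 and 120859335. The counts and lengths of these neighbourhoods may therefore include copies of the same sequence.

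**Figure D3:**
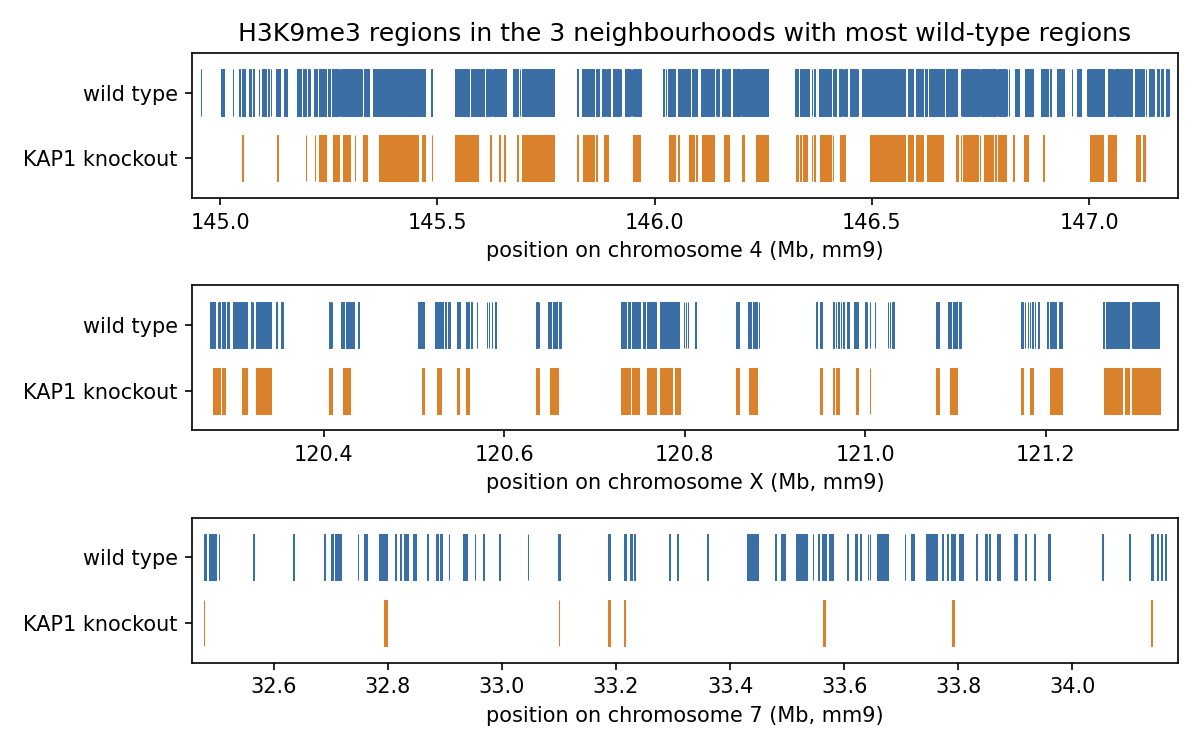
Positions (Mb, mm9) of H3K9me3 regions in the wild-type (blue) and KAP1 knockout (orange) list in the 3 neighbourhoods with most wild-type regions, each region drawn to scale with a thin outline that slightly widens the narrow ones. Knockout regions cover 818 kb of the chromosome 4 and 220 kb of the chromosome X neighbourhood but 21.3 kb of that on chromosome 7.

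Among the 24 clusters with at least 20 wild-type regions, the share with a partner ran from 0% to 65.4%, with a median of 20%. Of these, 3, chosen after their values were seen, held no knockout region at all. One lay on chromosome 7 from 11363110 to 12211575 and held 33 wild-type regions over 109 kb. Another, on chromosome 7 from 48244909 to 48593642, held 22 regions over 69.0 kb, and the other, on chromosome 3 from 15341565 to 15757376, held 20 regions over 54.5 kb. The absence of a call in these places does not show that the mark was absent, since the lists give no signal below the threshold of the region calling.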

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

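The changes that concern dense neighbourhoods, local placement, recurring arrangements and the smallest knockout gap were chosen after the data were seen. The ratio of region numbers, 6.20, was 7.03 on autosomes and 5.16 after neighbours up to 10 kb apart were joined. The share of wild-type regions with a knockout partner, 17.5%, was 19.8% among regions at or above the median width of their list, 14.6% on autosomes, 14.2% after joining, 15.1% without the 3 densest neighbourhoods, 13.5% when 50% of the wild-type region had to be covered, 9.95% with reciprocal overlap of 50%, 26.1% when a gap of up to 10 kb counted, and 52.6% among the widest wild-type regions, as many as there are knockout regions. The overlap, 32.5 times random placement, stayed above it under every setting run, from 3.63 times (local placement) to 214 times (reciprocal overlap). The width difference kept its direction and its side of the threshold under other overlap rules and on autosomes, and it exceeded placement anywhere on the chromosome but not local placement. The number of chromosomes called, 7, was 4 after joining and 4 without the 3 densest neighbourhoods; X, Y and 15 were among those called each time. Chromosome Y held 6.45% of the knockout regions and 4.54% of the knockout bases. The excess of clusters, 2.18 times random placement, was 5.37 times with a gap limit of 50 kb and 15.0 times for clusters of 5 or more, and reversed to 0.53 times with a gap limit of 500 kb, where the limit exceeds the average random median gap of 402 kb, so that randomly placed regions chain together. The share of clusters that held a wild-type region with a knockout partner, 50.7%, was 57.7% among clusters of 5 or more. Of 52 values under changed settings, 14 moved, 1 reversed and 37 stayed within their interval, within 1.5 times, or on their side of the threshold. For the other changes the cause was not tested. Alternatives on a score and on gene lists or sequence were not run, since the lists hold no score and no mm9 annotation or genome was used. No paired analysis was possible because each genotype has 1 H3K9me3 library. Read depth limits every value, and it is unknown.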

Other observations

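Of the tests in this part, that of recurring arrangements was chosen only after the pattern was seen. The width comparisons with random placement and those over all shared stretches were also added after the data were seen. The group of regions on chromosome 3 was picked after its values were seen. Regularly spaced regions on chromosome 3, as in a tandem array, alternated strictly between regions called in both lists and in the wild-type list alone. Whether the underlying sequence is a tandem array was not examined, since no genome sequence was used. Between 113056042 and 113165179 (mm9) the wild-type list held 7 regions, in turn 11.3 kb and 11.4 kb wide, with a repeat distance of 32.6 kb. The 3 regions of 11.4 kb each had a knockout partner (9.40, 9.40 and 7.00 kb wide), and the 4 regions of 11.3 kb had none. If copies of a sequence share their reads, as considered below, these 7 regions are not separate observations. On chromosome 7 the 4 wild-type regions of about 19 kb without a partner formed 2 pairs, 19111 and 19385 bp in the first and 19117 and 19389 bp in the second, 226890 and 226895 bp apart.

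The mitochondrial chromosome, which carries no histones, held 3 regions (4463 bp) in the wild-type list and 1 (497 bp) in the knockout list. These are 27.8% and 3.10% of the bases up to its last region, against 0.436% and 0.183% of the nuclear chromosomes. They are part of the 3748 and 605 regions counted above. Loss of the mark cannot account for a difference at these regions. With 3 against 1 region in 1 library each, they are too few to weigh the explanations below.

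Successive regions recurred elsewhere with the same widths and spacing. Within 20 bp for both widths and the gap, 344 wild-type regions (9.18% of the list, 10.5% of covered bases) belonged to such a recurring arrangement, against at most 24 in 1000 shuffles of the widths within chromosomes; in 131 of the 132 matches both members lay on the same chromosome, 97 of these regions lay on chromosome 7 and 50 on chromosome 4, and 14 knockout regions recurred. A candidate explanation is that near-identical copies of one sequence in the reference share their reads, so that 1 enriched sequence appears as several regions; the treatment of such reads by the aligner is not given in the sources used here. Counting each recurring arrangement once left 3565 wild-type and 598 knockout regions, a ratio of 5.96, and 17.4% of wild-type arrangements with a partner, so arrangements that match this closely do not account for the difference between the lists; looser or single-region copies were not tested. No biological explanation of the recurrence was tested.

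The knockout list is shorter by a factor of 6.20, and a difference in how neighbouring stretches were joined is argued against as its whole cause: after neighbours up to 10 kb apart were joined in both lists, 2429 wild-type and 471 knockout regions remained, a ratio of 5.16. A lower depth or enrichment of the knockout library stays open: it predicts narrower regions in the knockout where both lists have one, and the median log2 width ratio was -0.16 (95% bootstrap interval -0.24 to -0.10) in 1-to-1 pairs. Over all 543 shared stretches the median was -0.12, although 92 knockout regions span 2 or more wild-type regions. The narrowness of the missing regions decides little, since the width difference, 1.80 on the log2 scale, exceeded placement along whole chromosomes (0.87) but not local placement (1.80). Loss of the mark in cells without KAP1 is the biological explanation the design names; it may give the same picture and stays open as untested, since 1 library per genotype without read counts cannot separate them.

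Retention over chromosomes was uneven by number of regions, with 44.1% of wild-type regions on X and 14.6% on autosomes having a partner, while by covered length chromosome 1 (wild type over knockout 1.23) differed less between the lists than X (1.30). The test run held covered length of neighbourhoods roughly constant, not the width of single regions, so region width stays open as a cause. The test shows only that retention still differed between chromosomes among neighbourhoods grouped by covered length. Among 1498 neighbourhoods (regions up to 100 kb apart joined), retention permuted within 10 equal groups by covered length gave p = 0.0002 (10000 permutations), with 25 neighbourhoods on X holding a partner where 12.6 were expected from length, and 1 on chromosome 15 where 5.36 were expected. Chromosome 4, the autosome with the highest share of regions with a partner, had 9 such neighbourhoods where 13.04 were expected, and Y had 4 of 6 where 2.62 were expected. Signal height, copy number and a true difference between chromosomes stay open, because the lists carry neither signal nor input.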
